A study of Homo sapiens with 2 samples.

How the data were processed

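PRO-cap libraries were made from nuclear RNA of wild-type HUDEP-2 cells in 2 biological replicates, per the labels. Nuclei were run on with biotin-labelled nucleotides, and the labelled RNA was captured on streptavidin beads, ligated to adaptors, reverse transcribed, amplified and sequenced, per the labels' protocols. The submitters' processing notes name BWA 0.7.16a, Picard, SAMtools 1.17 and deepTools 3.5.4 and the build hg38. The deposited lists are named TSScall, but the version and threshold of the calling are not given in the sources used here. The same holds for the alignment settings, the treatment of reads with several matches, and whether and how the replicates were combined.

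The deposited data were 1 list of called transcription start positions for each strand, with a chromosome, a position, a name, a score and a strand per call. The position columns hold other values than measurements, namely the 1-base coordinates that the authors deposited, and they are printed 1-based in hg38. The score that the authors deposited is 0 for all 26395 calls, so that no strength, read count or depth per call was used. The numbers in the call names run without a gap, and calls of 1 strand lie at least 251 bp apart. No value per replicate was used, so that the precision given here is the counting error of numbers of calls and genes, as 95% Wilson intervals. A call is a yes or no at an unknown threshold, and a gene without a call can be transcribed below it.

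Analysis was restricted to the 26332 calls on chromosomes 1 to 22 and X. The other 63 calls, which include 35 on alternate or unplaced sequences and 4 on the mitochondrial genome, were left out of the comparisons. Genes were taken from a RefSeq gene table of the assembly GRCh38.p14, the same build as hg38, with 58419 genes on these chromosomes, 19821 of them protein-coding, after 679 entries on other scaffolds were removed. The table gives the outer coordinates of each gene. Strand, transcripts, exons and genome sequence were not used here, so that the planned tests of the sequence around calls and of the initiator of ribosomal protein genes, and the planned summary of call scores, were not run. The plan to match calls to transcript 5' ends of the same strand was replaced by the following definitions.

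A call was counted as the start of a gene when it lay within 500 bp of a gene end and pointed into the gene, that is, a forward call at the lower or a reverse call at the upper coordinate. A call pointed away from a gene end when it ran outward and lay up to 1000 bp outside or 500 bp inside that end. Remaining calls were inside or outside genes. Distal calls were more than 1000 bp from every gene end. A divergent partner was the nearest opposite-strand call 0 to 300 bp upstream, and a convergent partner one 1 to 300 bp downstream. A distal divergent pair was a reverse and a forward call, both distal, in the divergent arrangement. Positions of calls after a move of 10 kb gave the background of gene ends and partners.

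The tests, the alternatives, 22 gene lists with 506 entries and the rule for named genes were fixed before the data were examined, except where another choice is named as made later. All listed symbols matched the gene table. The rule named all globin genes and all listed erythroid transcription factors. For each other list it named all genes with a call where these were 5 or fewer, all without a call where these were 5 or fewer, and otherwise the first 4 by alphabet on each side. It also named the 10 protein-coding genes with most calls at their ends, the 10 listed erythroid genes with most distal pairs nearby and the genes at the 10 largest clusters of distal calls. Some items that the rule names are not reported here. Each list was set against all other protein-coding genes with Fisher's exact test, two-sided, adjusted by the Benjamini-Hochberg method over the lists, at a threshold of 0.05. The rule that calls on alternate sequences count against a lack of transcription only where the gene table places them in the run was set after these calls were counted. No call could meet this rule, since gene entries on other scaffolds had been removed. Random windows and matched gene sets were drawn 10000 times with a fixed seed.

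Alternatives were windows of 200 and 1000 bp, ends of protein-coding genes only, partner distances of 150 and 500 bp, a distal limit of 2000 bp, other sizes of the globin windows, pair distances of 20 and 100 kb, a cluster distance of 5 kb and lists without near-identical copies. The steps were tested on simulated data. With starts planted at the ends of the 19821 protein-coding genes for the comparison of lists, 100% of genes given a call were found and 3.15% of the others were found with a neighbour's call. All starts were planted well within the 500 bp window, so that full recovery was built in. Starts deeper inside a gene were not simulated. All 20 lists of 20 genes with a planted share of 90% against 40% elsewhere were called and 0 of 20 null lists were. For partners, a planted divergent share of 50% over 8077 calls came back as 51.3%. For distal pairs, planted shares of 40% in 360 genes and 10% in 8087 others came back as 36.4% and 13.3%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.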

Results

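PRO-cap, a run-on assay that captures nascent RNA from its 5' end, was applied to wild-type HUDEP-2 cells, an immortalised line of human erythroid progenitors. The series held 2 biological replicates of this 1 group and no treatment or second cell type, so that the results describe where transcription started in these cells. The deposited call set, which names no replicate, held 26395 called start positions for the cell line. Each was 1 base long, with 13229 on the forward and 13166 on the reverse strand. The calls carried no read count or strength and no value per replicate, so that the depth behind each call is unknown and no spread between replicates can be given. Intervals below are 95% Wilson intervals and cover counting error only. On chromosomes 1 to 22 and X, 13190 of 26332 calls (50.1%, 49.5 to 50.7) were forward (exact binomial test against equal shares, two-sided, p = 0.772). By chromosome the forward share ran from 48.2% to 53.7%, and no chromosome departed from equal shares (exact binomial tests, smallest unadjusted p = 0.0674, all adjusted p = 1).

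Most calls lay at the ends of annotated genes. Of the 26332 calls, 12048 (45.8%, 45.2 to 46.4) lay within 500 bp of a gene end and pointed into the gene, the place and direction of a promoter. A further 5536 (21.0%, 20.5 to 21.5) pointed away from a nearby gene end, 6872 (26.1%, 25.6 to 26.6) lay elsewhere inside genes and 1876 (7.12%, 6.82 to 7.44) lay outside genes. Distal calls, more than 1000 bp from every gene end, numbered 6476 (24.6%, 24.1 to 25.1), of which 4893 were inside genes and 1583 outside. The gene table gave each gene's outer ends without its strand, exons or transcripts, so that a distal call inside a gene includes any promoter of a shorter transcript of that gene.

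A start was called for 8207 of 19821 protein-coding genes (41.4%, 40.7 to 42.1), counting calls at a gene end that pointed into the gene. Of the 19 genes of haem synthesis and iron uptake, 17 had a called start (89.5%, 68.6 to 97.1), among them ALAS2, which catalyses the first step of haem synthesis in red cells, ALAD, the next enzyme of the pathway, FECH, which inserts iron, and the mitochondrial transporter ABCB10. CPOX, a later enzyme of haem synthesis, and SLC11A2, an iron transporter, had none. Among other erythroid genes 17 of 20 (85.0%, 64.0 to 94.8) had a called start, including AHSP, the chaperone of alpha globin, BLVRB, BNIP3L, which takes part in clearing mitochondria, and BPGM, while ARG1 and HEMGN were among those without one. The red cell membrane and blood group list had 18 of 29 (62.1%, 44.0 to 77.3), with ACKR1, AQP1, CD44 and the skeleton protein EPB41 called and ADD1, ADD2, ANK1 and BCAM not. Counting any call in or near the gene, the haem list had 19 of 19, the other erythroid genes 18 of 20 and the membrane list 26 of 29 (89.7%). There was 1 call each in CPOX and ADD1, 3 each in HEMGN and ADD2, 4 in SLC11A2 and 16 in ANK1, and none in ARG1 or BCAM. These 3 lists were higher than the other protein-coding genes by Fisher's exact test (two-sided, adjusted over 22 lists): adjusted p = 8.56e-05 for haem, 0.000374 for other erythroid genes and 0.0466 for membrane genes. The membrane list fell short of the threshold with a 200 bp window (exact test, adjusted p = 0.108) and among genes of at least 2000 bp (adjusted p = 0.131).

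In the list of erythroid transcription factors 15 of 22 (68.2%, 47.3 to 83.6, adjusted p = 0.0240, Fisher's exact test) had a called start. These were the master regulators GATA1 and KLF1, together with BACH1, FOXO3, KLF3, LMO2, MYB, NFE2, NFIX, RUNX1, SOX6, STAT5A, STAT5B and ZBTB7A, and the ubiquitin ligase TRIM58, which the list also holds. Without TRIM58 the share was 66.7% (exact test, adjusted p = 0.0345). The call of GATA1 lay at position 48786589 of chromosome X (hg38), 1 base outside the gene end, and that of KLF1 at 12887198 of chromosome 19, 3 bp inside it. BCL11A, GFI1B, IKZF1, LDB1, NFIA, TAL1 and ZFPM1 had no call at a gene end, although each held calls elsewhere, from 4 in BCL11A, GFI1B and ZFPM1 to 10 in IKZF1. Of the regulators of fetal globin, 19 of 25 had a called start (76.0%, 56.6 to 88.5, adjusted p = 0.00180, exact test), including the chromatin remodeller CHD4, the DNA methyltransferase DNMT1, the histone methyltransferase EHMT1 and the haem-regulated kinase EIF2AK1. BCL11A, the main repressor of fetal globin, BMI1, EHMT2 and HIC2 were among the 6 without one. This list shares BCL11A, KLF1, MYB, NFIA, NFIX and ZBTB7A with the transcription factor list, so that both results are not independent.

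Markers of other lineages were mostly without a called start. Of 15 megakaryocyte and platelet markers 1 had a start, the integrin ITGA2B, and CLEC1B, FLI1, GP1BA and GP1BB did not (adjusted p = 0.0120, exact test). Of 16 granulocyte and monocyte markers 1 had a start, the transcription factor CEBPA, and AZU1, CD14, CD68 and CEBPE did not (adjusted p = 0.00749, exact test). Of 17 lymphoid markers 1 had a start, the recombinase gene RAG1, and the CD3 chains CD3D, CD3E and CD3G of the T cell receptor complex did not (adjusted p = 0.00473, exact test). Among hepatocyte markers TF, which encodes transferrin, was called and AHSG, ALB, APOA1 and APOA2 were not (1 of 14, adjusted p = 0.0194, exact test). Among neuronal markers SYN1 was called and CAMK2A, DLG4 and GAD1 were not (1 of 13, adjusted p = 0.0276, exact test), and no muscle or stromal marker was called (0 of 14, with ACTA1, CKM, COL1A1 and COL1A2 among them, adjusted p = 0.00179). These 6 lists were lower than other protein-coding genes by Fisher's exact test. The calls of RAG1 and TF had divergent partners, at 84 and 81 bp. Whether these calls start the marker genes or belong to a neighbouring start was not tested. Stem and progenitor markers had 3 of 15 (20%, 7.05 to 45.2, adjusted p = 0.129, exact test), namely GATA2, HLF and MLLT3 but not AVP, CD34, CRHBP or ERG. Mast cell, basophil and eosinophil markers had 1 of 10 (adjusted p = 0.0660, exact test), GATA2 again, with CLC, CPA3, EPX and FCER1A uncalled. Counting any call in or near the gene, the neuronal list no longer passed (exact test, adjusted p = 0.0534) and 3 further lists did, the mast cell list (lower, adjusted p = 0.0110), interferon-stimulated genes (lower, adjusted p = 0.0484) and the immediate early and heat shock list (higher, adjusted p = 0.0425). GAD1 held 9 such calls and DLG4, APOA1, CRHBP and ERG 1 each. The other markers named here without a start held none.

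Genes of basic cell functions also had high shares. All 24 genes of DNA replication and mitosis had a called start (86.2 to 100), such as the mitotic kinases AURKA and AURKB and the cyclins CCNA2 and CCNB1 (adjusted p = 4.64e-09, Fisher's exact test). The list for RNA polymerase II, initiation and pausing had 19 of 20, with CCNT1, CDK7 and CDK9 among those called and NELFE, a subunit of the pausing factor NELF, not (adjusted p = 3.50e-06, exact test). Ribosomal protein genes had 74 of 86 (86.0%, 77.2 to 91.8), with FAU, RPL10, RPL10A and RPL11 called and RPL10L, RPL15, RPL26L1 and RPL39 not (adjusted p = 2.58e-16, exact test). Replication-dependent histone genes had 55 of 69 (79.7%, 68.8 to 87.5), with H1-2, H1-3, H1-4 and H1-5 called and H1-1, H1-6, H2AC1 and H2AC18 not (adjusted p = 1.17e-09, exact test). Glycolysis had 16 of 19 (84.2%, 62.4 to 94.5), with ALDOA, ALDOC, ENO1 and GAPDH called and ENO2, GPI and HK1 not (adjusted p = 0.000637, exact test). Apoptosis genes and p53 targets had 11 of 15 (73.3%, 48.0 to 89.1), with BAX, BCL2L1, BCL2L11 and GADD45A called and BBC3, BCL2, CDKN1A and FAS not (adjusted p = 0.0240, exact test). The immediate early and heat shock list had 11 of 18 (61.1%, 38.6 to 79.7, adjusted p = 0.114, exact test), with DUSP1, EGR1, EGR2 and FOS called and ATF3, DNAJB1, EGR3 and HSPA1A not. Interferon-stimulated genes had 4 of 16 (25%, 10.2 to 49.5, adjusted p = 0.223, exact test), among them IFI6, ISG15 and RSAD2, while IFI44, IFI44L, IFIT1 and IFIT2 had none. Some genes named here without a start held calls elsewhere in or near the gene. DNAJB1 held 5, BBC3 and HK1 4 each, RPL15 and RPL26L1 3 each, ATF3 and BCL2 2 each, and FAS and RPL39 1 each. The others named without a start held no call. NELFE, HSPA1A and EHMT2 lie in a run of 172 neighbouring genes on chromosome 6 without any called start, and with that run left out the immediate early and heat shock list was higher than other genes (73.3%, exact test, adjusted p = 0.0221). The run was chosen for its lack of calls, so that leaving it out could only raise the share of a list with members in it. With calls moved by 10 kb, 2.77% of protein-coding genes had such a call by chance, and 135 of the 8207 genes had one at both ends.

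**Figure D1:**
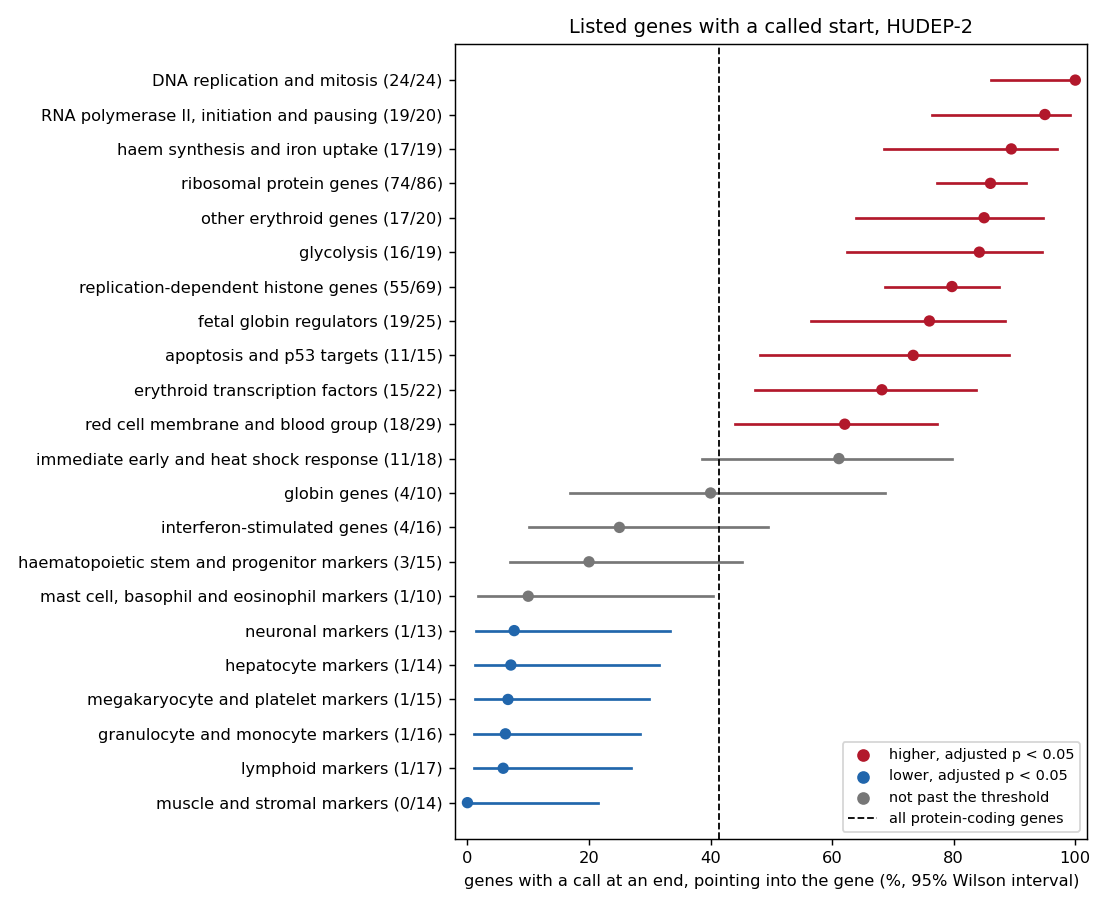
Share of genes in each of the 22 lists with a call at a gene end that points into the gene, in percent on the x axis, with points for the share, lines for the 95% Wilson interval and the number of genes in brackets. The dashed line marks the 41.4% of all protein-coding genes; 11 lists lie above it and 6 below it past the threshold of an adjusted p of 0.05.

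Inward calls at both ends of a gene were counted together, since strand was not used. Antisense calls at a 3' end can therefore be among them. Most protein-coding genes with a called start had a single such call, namely 6947 of the 8207. Of the others, 1179 had 2, 77 had 3 and 4 had 4. The genes with 4 were EBAG9UORF and LOC139427322, both very short genes in the table, the histone gene H4C1 and the lipid receptor gene S1PR4. AP5S1, ARL2, ARRDC2, B9D1, CAGE1 and CAND1, the first by alphabet among those with 3, complete the named genes. Calls of 1 strand were never closer than 251 bp to each other, so that these counts cannot exceed a few per window.

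Called starts lay close to the annotated gene ends. For all genes with such a call the median position was 4 bp inside the gene, and 42.7% of them lay within 10 bp. For protein-coding genes the median was also 4 bp inside (quartiles -1 and 32), with 3769 of 8207 (45.9%, 44.8 to 47.0) within 10 bp and 77.6% (76.7 to 78.5) within 50 bp. The start of HBB, the adult beta-globin gene, fell on the annotated end itself at position 5227071 of chromosome 11, and those of ALAS2, AQP1, NFE2 and AHSP each lay 1 base outside their gene. The starts of long noncoding RNA genes were more scattered, with 23.5% (21.6 to 25.6) of 1706 within 10 bp. At tRNA genes, which RNA polymerase III transcribes, 190 of 429 had a call within 10 bp, each of these 2 to 10 bp upstream of the gene, with a median over the 218 called tRNA genes of 6 bp upstream.

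**Figure D2:**
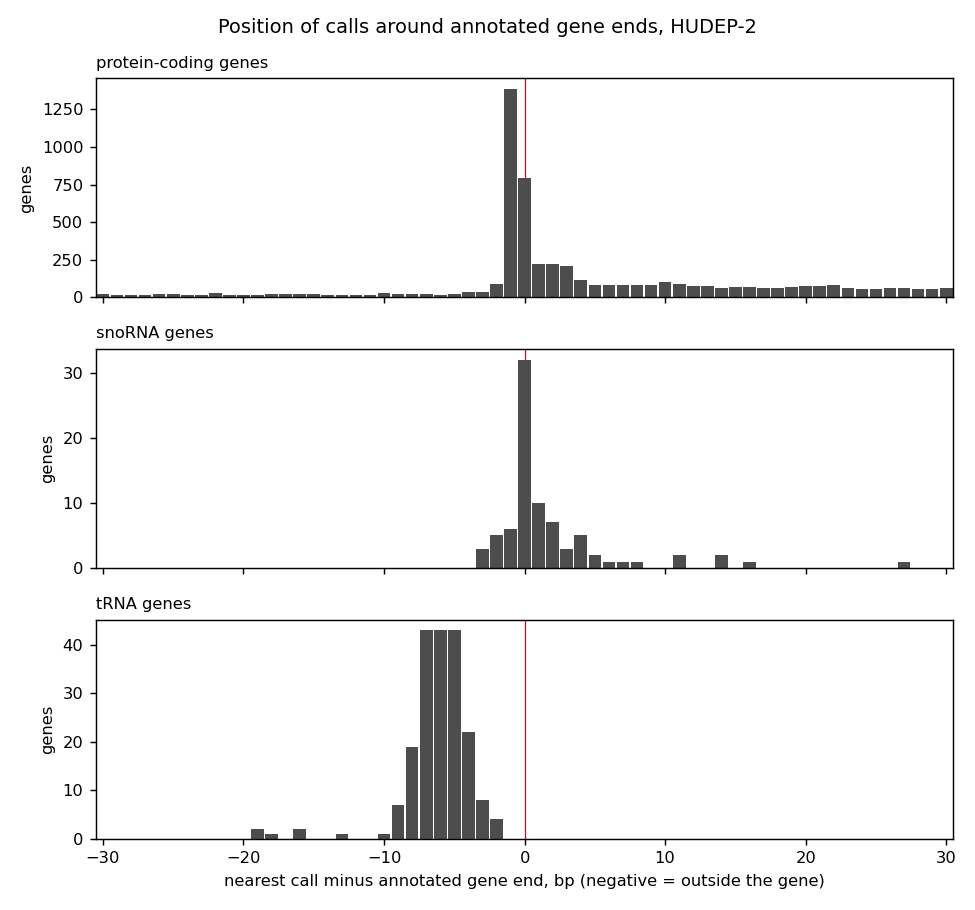
Number of genes by the position of their nearest inward call relative to the annotated gene end, in bp on the x axis with negative values outside the gene, for protein-coding, snoRNA and tRNA genes. Protein-coding genes peak 1 base outside the end (1387 genes, against 797 at the end itself), snoRNA genes peak at the end (32 genes) and tRNA genes 2 to 10 bp upstream.

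Start calls often came in divergent pairs, with a call on the opposite strand 0 to 300 bp upstream that pointed the other way. This held for 5915 of 12048 calls at gene ends (49.1%, 48.2 to 50) and 1898 of 6476 distal calls (29.3%, 28.2 to 30.4), an odds ratio of 2.33 (Fisher's exact test, two-sided, p = 2.76e-152). KLF1 had its partner at 112 bp, LMO2 at 80 bp and STAT5B at 127 bp, while the calls nearest to the ends of GATA1, NFE2 and ALAS2 had none. The median distance of the partner was 149 bp at gene ends and 146 bp at distal sites. The convergent arrangement was rarer, at 10.9% (10.3 to 11.4) of calls at gene ends and 8.31% (7.66 to 9.0) of distal calls, and moving calls by 10 kb left 0.606% and 0.865% with a divergent partner. Distal calls inside genes had a divergent partner in 29.9% and those outside in 27.6% of cases (exact test, adjusted p = 0.0923). Both calls of a distal pair, or of a pair that starts 2 genes, enter these counts, so that the p-values treat such linked calls as independent.

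**Figure D3:**
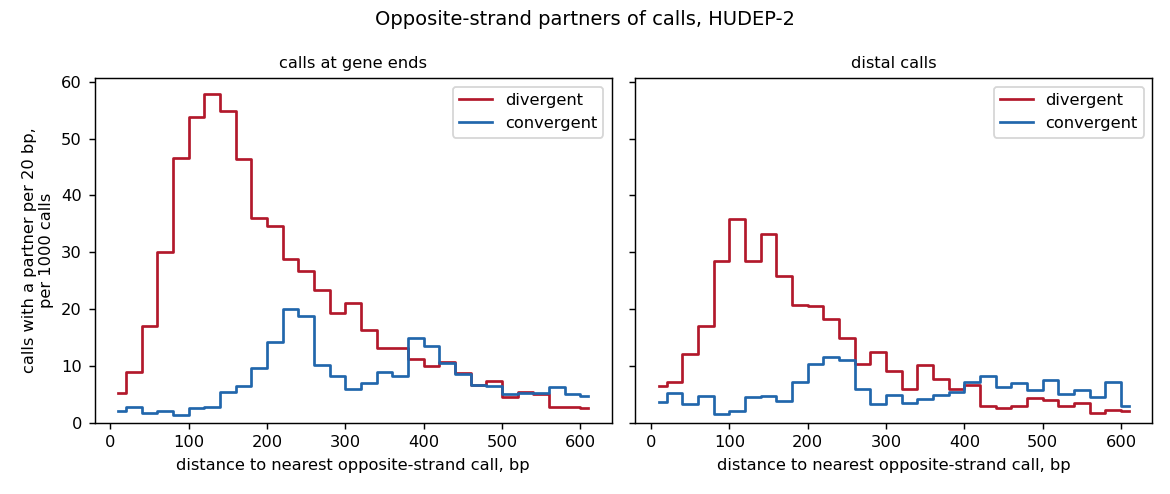
Calls with an opposite-strand partner per 1000 calls, in bins of 20 bp of the distance to the nearest such call on the x axis, for calls at gene ends and for distal calls. Divergent partners, in red, have median distances of 149 and 146 bp, and convergent partners within 300 bp, in blue, of 223 and 201 bp.

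At the beta-globin cluster the adult genes carried the calls and the embryonic and fetal genes carried none. HBB held 4 reverse calls, at its annotated 5' end and 297, 596 and 1406 bp into the gene, and HBD, the minor adult gene, had 1 at position 5234554, 71 bp outside its end. HBE1, the embryonic gene, and HBG1 and HBG2, the fetal genes, held no call. The noncoding gene BGLT3 held a divergent pair at 5244808 and 5244866. Upstream of HBE1, on the side of the locus control region that serves as the distal enhancer of the cluster, divergent pairs lay 6.0 to 6.1 kb (5275950 and 5276048) and 18.3 to 18.4 kb (5288254 and 5288334) away, with single calls at 10.8 kb (5280705, forward) and 33.7 kb (5303692, reverse). All of these 6 calls were distal and outside annotated genes. The window from 50 kb before to 50 kb after the cluster (chromosome 11, 5175464 to 5319945) held 13 calls, more than 98.7% of 10000 random windows of its size that hold a gene.

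At the alpha-globin cluster the minor genes HBM and HBQ1 had called starts and the main genes HBA1 and HBA2 and the embryonic gene HBZ had none. The call of HBM lay 2 bp outside the gene at position 165976 of chromosome 16, with a divergent partner 59 bp away, and that of HBQ1 17 bp inside at 180476, followed by reverse calls at 181019 and 181445. HBA1 and HBA2 are near-identical copies, as are HBG1 and HBG2, so that the lack of a call at these genes is uncertain as a measure of transcription. NPRL3, whose introns carry the enhancers of the alpha cluster, had a start at 138648 and distal calls within the gene at 105062, 113791 and 120214, the last 2 forward and 38.9 and 32.4 kb from HBZ. The window (102644 to 231179) again held 13 calls, above 99.1% of random windows. Among these, the calls at 229124, 229190 and 229449 lay at an end of LUC7L, and those at 138648 and 138783 at an end of NPRL3. For both clusters the random windows had to hold only a gene of any kind, had a median of 0 calls and were not matched on gene density. The ranks therefore do not tell globin genes from gene-rich surroundings. As a list, globin genes had 4 of 10 called (40%, 16.8 to 68.7, adjusted p = 1, Fisher's exact test).

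**Figure D4:**
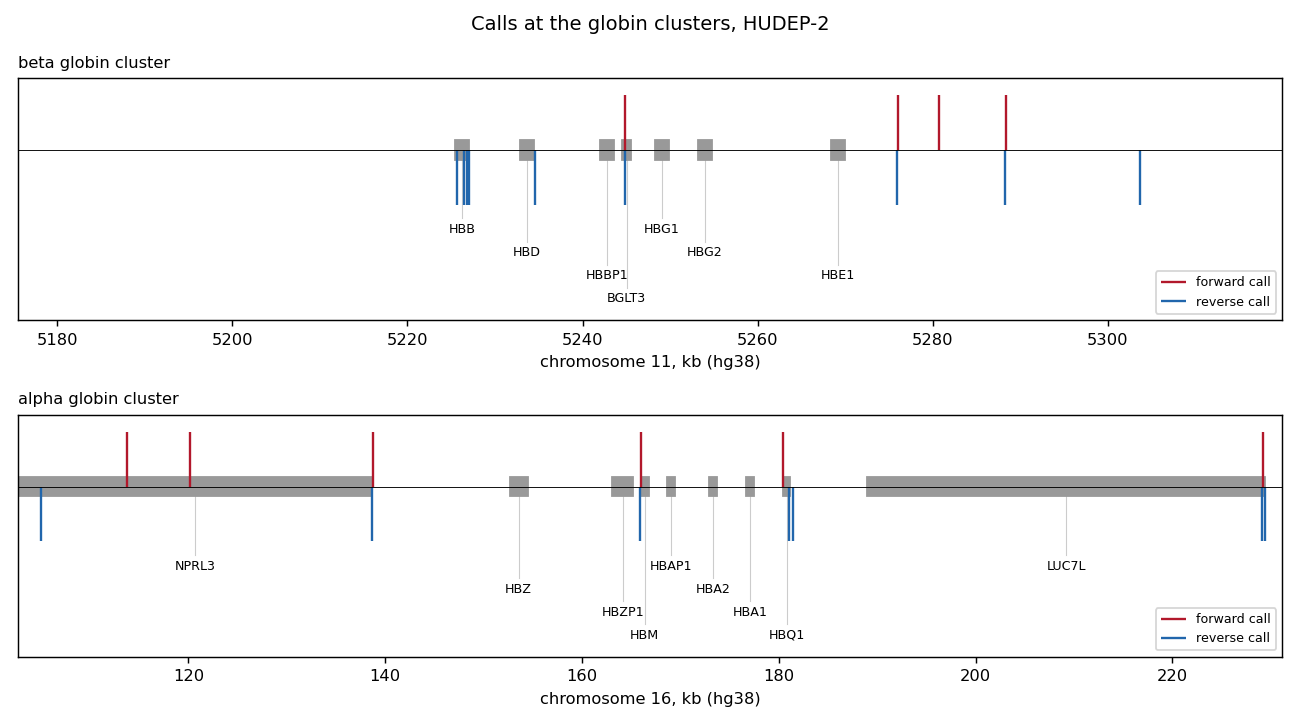
Maps of the beta-globin cluster (chromosome 11) and the alpha-globin cluster (chromosome 16) in hg38, in kb on the x axis, with grey boxes for genes and lines for forward calls (up, red) and reverse calls (down, blue). Each window holds 13 calls; none lies in HBG1, HBG2, HBE1, HBZ, HBA1 or HBA2.

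Divergent pairs away from gene ends, an arrangement found at active enhancers, lay near erythroid genes more often than near other genes. There were 921 distal divergent pairs, of which 213 lay outside genes. Of 67 genes with a called start in the 4 erythroid lists, 19 (28.4%, 19.0 to 40.1) had a pair within 50 kb, against 845 of 8140 other protein-coding genes with a start (10.4%; odds ratio 3.42, Fisher's exact test, two-sided, p = 3.89e-05). Random gene sets matched on the number of protein-coding genes within 100 kb had 10.3% (SD 3.63), and none of 10000 reached the observed share (one-sided permutation p = 0.0001, the smallest that these sets can give). SLC4A1, the anion exchanger of the red cell, had pairs 1.41 kb away inside the gene (44266588 and 44266870 of chromosome 17) and 48.6 kb away in UBTF. PRDX2, an abundant red cell antioxidant enzyme, had pairs 11.8 and 13.1 kb away in HOOK2, and SPTB, which encodes beta spectrin, pairs 34.5 and 37.7 kb away within its own gene. ALAD, BLVRB, ERMAP, FTH1, GYPC and ICAM4 had 1 pair each. By list, 7 of 18 membrane genes (adjusted p = 0.0329), 5 of 15 transcription factors (adjusted p = 0.164), 5 of 17 haem genes (adjusted p = 0.189) and 2 of 17 other erythroid genes (adjusted p = 1) had a pair, by exact tests over 21 lists. With pairs outside genes alone the shares were 10.4% and 2.59% (exact test, p = 0.00190), and with partners within 150 bp 13.4% and 5.80% (exact test, p = 0.0156). Some pairs inside genes can be promoters of shorter transcripts, since the gene table holds only outer gene ends.

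Distal calls also gathered in clusters. Joined where under 10 kb apart, the 6476 distal calls formed 3714 groups, of which 2250 were single calls and 153 held 5 or more. The largest held 15 calls over 11.6 kb on chromosome 1 (50968131 to 50979768) and overlapped CDKN2C, an inhibitor of cell cycle kinases. Other large clusters held 13 calls in KCNH2 on chromosome 7, 12 between ZSWIM4 and NANOS3 on chromosome 19 and 11 at KLF16 on the same chromosome. Clusters of 10 calls lay in LTBP4, at SLC11A1 and CTDSP1, and between RNF144A and ID2, where the nearer gene ID2, an inhibitor of differentiation factors, was 138 kb away. Clusters of 9 calls lay in RBPJ, the DNA-binding effector of Notch signalling, and in SIN3A, a corepressor. No test was run on these clusters.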

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

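The tests in this part were all chosen after the result was seen. Calls at short RNA genes, which the gene lists did not use but the counts by place and partner did, and calls on sequences outside the main chromosomes, which no planned comparison used, stood out as signal. They numbered 190 tRNA genes and 76 snoRNA genes with a call within 10 bp of their end, 4 calls on the mitochondrial genome and 35 calls on alternate and unplaced sequences.

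The calls within 10 bp of tRNA genes lay 2 to 10 bp upstream, those at snoRNA genes peaked at the gene end (32 of the 107 called), and PRO-cap is meant to select capped RNA, which neither RNA carries as a rule. Promoters of RNA polymerase II that happen to lie nearby would spread over the neighbourhood, but of the tRNA genes with a call within 200 bp, 92.7% (88.3 to 95.5) had it within 10 bp. The calls were thus not spread. These 190 of 205 genes are the flagged ones, so that the share restates the pattern and is no separate test of such promoters. A candidate explanation is that 5' ends of RNA without a cap entered the libraries: 4 of the 4 mitochondrial calls, from a genome whose RNA has no cap, lay within 1 bp of the end of a tRNA gene (TRNF, TRNS2, TRNY and TRNP), where random positions reached at most 2 (one-sided permutation p = 0.0001, the smallest that 10000 random sets can give). With 4 calls this test is small and shows such ends only for mitochondrial RNA, and no other biological explanation was tested. Leaving out calls at tRNA, snoRNA, snRNA and miRNA ends moved the share of calls that point into a gene end to 45.1% and the odds ratio of a divergent partner to 2.38.

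A run of 172 neighbouring protein-coding genes on chromosome 6, from GPX6 to ZBTB9 (28503296 to 33457544, 4.95 Mb), which spans the major histocompatibility complex, had no called start (upper limit 2.18%) and no call of any kind from 28490104 to 33571322 between the calls on either side (EHMT2, IER3, HSPA1A, HSPA1B, NELFE and RPS18 are listed members), against starts in 410 of 870 genes (47.1%, 43.8 to 50.4) on the rest of the chromosome. A lack of transcription cannot be told apart from technical causes. On 5 alternate sequences of chromosome 6 lay 11 calls, more than the 3 that a count of 0 allows. Gene entries on other scaffolds had been removed, so that none of these calls could be placed in this region, wherever they lie. Their number therefore decides nothing. RPS18 and NELFE, whose lists had starts in 87.1% and 100% of genes outside the run, go against a lack of transcription as 2 genes only. A candidate explanation is that reads that match several copies of a sequence were not called: of 31 genes with a near-identical copy elsewhere, chosen by name and without histone or globin genes, 3.23% (0.572 to 16.2) had a called start, only POM121, against 41.5% of the others (Fisher's exact test, p = 2.90e-06). Other multicopy groups were often called, with 55 of 69 replication-dependent histone genes (79.7%) and 218 of 429 tRNA genes (50.8%), and since sequence was not used here, how alike their copies are was not measured. The explanation therefore stays open for this run and for HBA1, HBA2, HBG1 and HBG2, as does the treatment of such reads in the alignment, and no other biological explanation was tested.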

How the results depend on the processing

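The alternatives with any call in or near a gene, genes of at least 2000 bp, short RNA ends left out, forward calls only, pairs outside genes, the call-free run left out, all sequences, the membrane list left out and TRIM58 left out were chosen after seeing the data. No paired analysis was possible because the series has 1 group and no value per replicate, and leaving out a replicate was not run for the same reason. A stricter score (all scores are 0), the sequence, initiator and score alternatives (no sequence or score was used) and transcript 5' ends were not run either, and merging calls within 50 bp removes none, as calls of 1 strand are at least 251 bp apart. Of the other values of main results, 51 stayed within their interval, within 1.5 times their count or on their side of the threshold and 25 moved, and none reversed. Clusters of 5 or more calls, 153 in the report, were 110 with a distal limit of 2000 bp and 131 when joined under 5 kb. For single lists 144 results were the same, 4 gained and 3 lost significance. With a 200 bp window the calls pointing into a gene end fell to 36.0% and those pointing away came to 26.3%, genes with a start to 38.2% and gene-end calls with a divergent partner to 51.4%. With 1000 bp these were 55.4%, 16.7%, 44.1% and 47.3%. With ends of protein-coding genes only they were 35.7% and 22.5%, with 32.9% distal calls, 31.6% of these with a partner, and 45.9% of starts within 10 bp (45.4% for forward calls). A wider window or more gene ends take in more calls by construction, but for the partner shares and the share within 10 bp the cause was not tested. Leaving out genes with near-identical copies took the globin and histone clusters out whole, as planned, whether or not each member has such a copy, so that these lists have no value there. Partner distances of 150 and 500 bp gave 25% and 60.8% at gene ends and 15.2% and 35.0% at distal calls. A distal limit of 2000 bp left 18.5% distal. Windows of 20 kb around the globin clusters ranked above 99.6% (beta) and 98.0% (alpha) of random windows, and windows anywhere gave 98.9% for beta, of which the cause was not tested. Any call in or near the gene gave 52.6% of genes, genes of at least 2000 bp 43.0%, and leaving out short RNA ends 45.1% of calls at gene ends. Distal pairs near erythroid genes kept their side of the threshold at 20 kb, 100 kb, 150 bp, 500 bp, a distal limit of 2000 bp, outside genes only, and without the membrane list (24.5% against 10.4%, exact test, p = 0.00380).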

Other observations

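The gene families, the position tests, the comparison without single lists and the tests of erythroid pairs against single lists in this part were chosen after the data were seen. The tests of partners at erythroid genes and of distal pairs near other lists were set before the partner shares and the shares near other lists were seen.

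Mitochondrial ribosomal protein genes had a called start in 69 of 76 cases (90.8%, 82.2 to 95.5), complex I genes in 40 of 46 (87.0%), translation initiation factors in 45 of 55 (81.8%) and proteasome subunits in 33 of 48 (68.8%, 54.7 to 80.1). Cytosolic aminoacyl-tRNA synthetases had one in 15 of 17 (88.2%). The numbered zinc finger genes had one in 276 of 477 (57.9%, 53.4 to 62.2, against 41.0% of other genes). None of 387 olfactory receptor genes (upper limit 0.983%) or 94 keratin-associated protein genes (upper limit 3.93%) had a called start. Keratins had 1 of 55, KRT13, protocadherins 1 of 65, PCDHGA10, and interleukins and chemokines 2 of 76, IL5 and IL7. Other long runs of protein-coding genes without a call in or near them, besides the 172 genes on chromosome 6, held 66 genes over 9.26 Mb on chromosome 11, 59 over 3.11 Mb on chromosome 17 and 50 over 1.16 Mb on chromosome 8. Whether these runs lack transcription or lack calls for technical reasons was not tested. The HOX genes, which set positional identity and mark blood progenitors, had called starts at HOXB2, HOXB3 and HOXB4, with 0 of 11 genes in HOXA, 0 of 9 in HOXC and 0 of 9 in HOXD. HOXA3 and HOXA4 each had 1 call elsewhere in or near the gene, and HOXB was not tested against the other clusters. All of these families differed from other protein-coding genes by Fisher's exact test over 15 families (largest adjusted p = 0.0140, for HOXC and HOXD) except HOXB (3 of 10, adjusted p = 0.538). The genes of a HOX cluster are neighbours, and the test counts them as independent, so that its p-values overstate the evidence from 1 locus. The same can hold for other families with neighbouring genes. The genes named here were chosen after their values were seen.

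Inside the 8072 protein-coding genes with a start at 1 end, more than 500 bp from that end, calls opposite to that start (2532) outnumbered those in its direction (1983, or 43.9%, 42.5 to 45.4). The direction was taken from the end with the call, since strand was not used. Starts of overlapping genes were included, and a call counted once for each gene that held it. The counts therefore do not measure antisense starts apart from those of overlapping genes. Among protein-coding genes with a start, 544 pairs had their starts facing away from each other within 300 bp.

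It was asked whether starts of erythroid genes have a divergent partner less often than others. Of 71 erythroid and globin genes with a start, 36.6% (26.4 to 48.2) had one, against 50.8% of other genes (Fisher's exact test, two-sided, p = 0.0229). The difference rested on the membrane and blood group list, with 3 of 18 (exact test, adjusted p = 0.0828 over 21 lists). Without that list the share was 43.4% of 53 genes (exact test, p = 0.335), and without each of the other lists it was 33.3% to 37.3% (largest p = 0.0362). Ribosomal protein genes had a partner in 48 of 74 cases (64.9%, exact test, adjusted p = 0.150).

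It was also asked whether any list of actively used genes has as many distal divergent pairs within 50 kb as the erythroid lists. Genes of the replication, polymerase and ribosomal protein lists had one in 13.7% of 117 cases (8.60 to 21.1), below the 28.4% of erythroid genes (Fisher's exact test, two-sided, p = 0.0191). Ribosomal protein genes alone had 9 of 74 (12.2%, exact test, p = 0.0201), and without them the fewer genes of the replication and polymerase lists had 7 of 43 (16.3%, 8.12 to 30, exact test, p = 0.173). Taken singly, polymerase genes had 2 of 19 (10.5%, exact test, p = 0.139), DNA replication genes 5 of 24 (20.8%, exact test, p = 0.594) and immediate early and heat shock genes 3 of 11 (27.3%, exact test, p = 1), while other erythroid genes had 2 of 17 (11.8%). Active genes thus did not all have as many pairs as the erythroid lists, and whether the erythroid lists stand apart from each of the smaller lists stays open.

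At protein-coding gene ends 1387 calls lay 1 base outside the annotated end and 797 on it, so that 63.5% (61.5 to 65.5) of these lay outside. A shift of all deposited coordinates is argued against by snoRNA genes, where 15.8% (7.44 to 30.4) did (Fisher's exact test, p = 2.75e-09), and a different treatment of the strands by the equal shares on both, with forward minus reverse at -0.0247 percentage points (95% interval -4.06 to 4.01). Left are a base added opposite the cap during reverse transcription and the way in which gene ends were annotated. Both predict the 72.4% (65.6 to 78.4) found at long noncoding RNA genes. The sequence needed to separate them was not used here. The labels' protocols place the ligation of adaptors before reverse transcription. A 5' end joined to an adaptor carries no cap, so that this order of steps goes against the added base. No biological explanation was tested.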
